A study of Homo sapiens with 7 samples.

How the data were processed

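RNA of A549 cells, an established human non-small-cell lung carcinoma line, was measured on 7 one-colour Agilent expression arrays. Per the labels, the cells grew in serum-supplemented medium. They were left untreated (2 arrays) or received 25 µM of the peptide R6-NLS-p53(380–386-3Ac) for 12 h (3 arrays) or 24 h (2 arrays). The peptide name denotes an acetylated stretch of the carboxy-terminal end of p53, joined to a nuclear localisation signal. Trypsinised cells were stored in RNAlater, RNA was extracted with a column kit and DNase, and an oligo-dT primer started the Cy3 labelling, per the labels' protocols. Such labelling favours polyadenylated RNA. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The time at which the untreated cells were taken is not given in the sources used here.

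The authors scanned the arrays and deposited one scanner table per array, with spot intensities on a linear scale. Per the file headers, Agilent Feature Extraction 11.5.1.1 subtracted the background from these intensities, removed spatial and multiplicative trends, and put surrogate values in place of signals not above background. The headers name the annotation build hg19. The deposited series values are on the log2 scale, with 1 value per gene name and array. How this table was made is not given in the sources used here. For the 26068 names with a single probe it equalled the log2 processed signal of its array minus a constant (r = 1), so its direction and log base are known and it is not centred per gene. Its constants differed from those used here by −0.15 to −0.22. The medians of its columns ran from −4.09 to −3.57. For names with several probes, 98.7% of 19484 values lay within 0.1 of the mean over the probes well above background alone. Which probes enter a name there thus differs from array to array. All columns of that table belong to the 7 arrays.

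Each array held 62976 spots, of which 4259 control spots were left out of all tests. Between 325 and 527 outlier spots per array were left out, and no spot was saturated. Spots of one probe were averaged on the log2 scale, which gave 50383 probes after 216 without a usable spot on every array were dropped. Names came from a current gene table for 28067 probes by accession, for 2606 by current symbol and for 617 by an older symbol. A further 17189 probes kept only the name in the file, and 1904 had no gene name. The main values were log2 of the processed signal minus the 75th percentile of the array, so a level of 0 is that percentile. A probe was tested where a share of at least 0.5 of its spots was well above background on every array of at least 1 group. That left 27303 probes, 917 of them unnamed and kept apart. The brightest probe stood for its gene, which gave 19658 genes, 15499 of them with a current symbol. Positions are those of the probes on hg19 as the files give them. No exon annotation of that build was used here.

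limma 3.58.1 in R 4.3.3 fitted the 3 groups together with lmFit and eBayes. The residual degrees of freedom were 4 and the prior ones 1.85. P-values are two-sided and adjusted by the Benjamini-Hochberg method over genes, with a threshold of 0.05. Where a gene was not well above background on any array of a group, its fold is a bound. The bound sets the mean of the brighter group against the mean of, per array, the higher of the lowest signal well above background and the gene's own signal. Such folds are written "at least". Tables were read with the R package data.table, version 1.17.8 and plots drawn with matplotlib 3.10.9 in Python 3.11.15.

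Gene groups were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over 30 lists and 3 comparisons. The lists were p53 targets, p53 regulators and partners, base excision repair, nucleotide excision repair, double-strand break repair, G2 and mitosis, G1/S and DNA replication, replication-dependent histones, pro-apoptotic and anti-apoptotic genes, unfolded protein and ATF4 response, heat shock, NRF2 and antioxidant, NF-kappaB and inflammatory, interferon-stimulated, cholesterol and fatty acid synthesis, hypoxia and glycolysis, immediate early, autophagy and lysosome, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, oxidative phosphorylation, spliceosome, proteasome, TGF-beta with matrix and mesenchymal, epithelial and alveolar, metallothioneins, leukocyte markers, fibroblast and endothelial markers, and reference housekeeping genes. They held 769 entries, 48 of them with no tested probe. The lists, the tests, the rule for named genes and the alternatives below, except those named as added later, were fixed before the data were examined.

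The rule for named genes took, per comparison, the 6 largest rises and the 6 largest falls among genes with an ordinary symbol. Such genes passed the adjusted threshold, did not overlap between groups and were well above background throughout. It also took the 2 largest bounds per direction, or, where fewer than 3 genes passed in a direction, the 3 with the smallest p. From each list that passed camera it took the 3 members with the smallest p, and the same always from the p53 target, base excision repair, G2 and mitosis, and pro-apoptotic lists. SUB1, CDKN1A, MDM2, BAX, BBC3 and GDF15 were always named. Some genes this rule chose are not reported here. List members named beyond these were chosen after their values were seen.

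The 7 arrays lay on 2 slides. Slide 1 held both untreated arrays and 12 h replicate 1, and slide 2 held 12 h replicates 2 and 3 and both 24 h arrays. All were scanned on 1 day, in 2 scans. The slide was therefore also fitted as a fixed term, and 12 h was set against untreated within slide 1 and 24 h against 12 h within slide 2. No slide held both untreated and 24 h arrays. With the slide term, the 12 h estimate rests on 12 h replicate 1 alone and equals the estimate within slide 1. Without 12 h replicate 1, all untreated arrays lay on slide 1 and all treated arrays on slide 2. Fits without that array therefore cannot separate treatment from slide, and calls kept or gained there do not test a slide effect.

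Other alternatives were normexp background correction with an offset of 50, quantile normalisation, scaling by the median, no filter and a stricter filter on dim probes, the mean of a gene's probes, and the deposited series table. The replicate number as a block, fits of only the groups compared, eBayes with an intensity trend and robust settings, an absolute log2 change of at least 1, and leaving out each array in turn were also run. For the lists, an estimated correlation and fry were added. Comparisons that share the untreated arrays were set beside 100 simulations of unchanged groups.

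The fit was tested on simulated data in which 50 of 19658 genes per size were changed by a known amount. At 12 h against untreated, changes of log2 0.5, 1, 2 and 3 were recovered in 6%, 70%, 90% and 94% of the genes. At 24 h against untreated the shares were 0%, 68%, 92% and 98%, and at 24 h against 12 h they were 6%, 68%, 84% and 88%. A simulated list of 30 genes shifted by −0.4 was called in each comparison, also with an estimated correlation, and 0 of 29 unchanged lists were called by camera. The simulated noise was independent between genes and held no slide effect. False list calls among correlated genes could therefore not be tested. Far fewer genes were changed than limma called in the data, so the recovered shares may not hold for the data. The number of arrays limits the precision.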

Results

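Gene expression was profiled in A549 cells, an established human lung carcinoma line, on 7 one-colour arrays. The series concerns PC4, the chromatin-associated coactivator encoded by SUB1, and its part in the p53-dependent answer to genotoxic stress. Untreated cells had 2 arrays, and cells given 25 µM of the acetylated p53 peptide R6-NLS-p53(380–386-3Ac) had 3 arrays at 12 h and 2 arrays at 24 h. Between 49.5% and 58.9% of the 50383 probes were well above background on an array, and the 75th percentile of the signal lay between 219 and 252. Levels below are log2 signals relative to that percentile, changes are log2 differences, and spreads are SDs over the arrays of a group (n = 2, 3 and 2 for untreated, 12 h and 24 h). A second set of estimates comes from the same fit with a term for the slide, because both untreated arrays lay on slide 1 and 4 of the 5 treated arrays on slide 2.

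**Figure D1:**
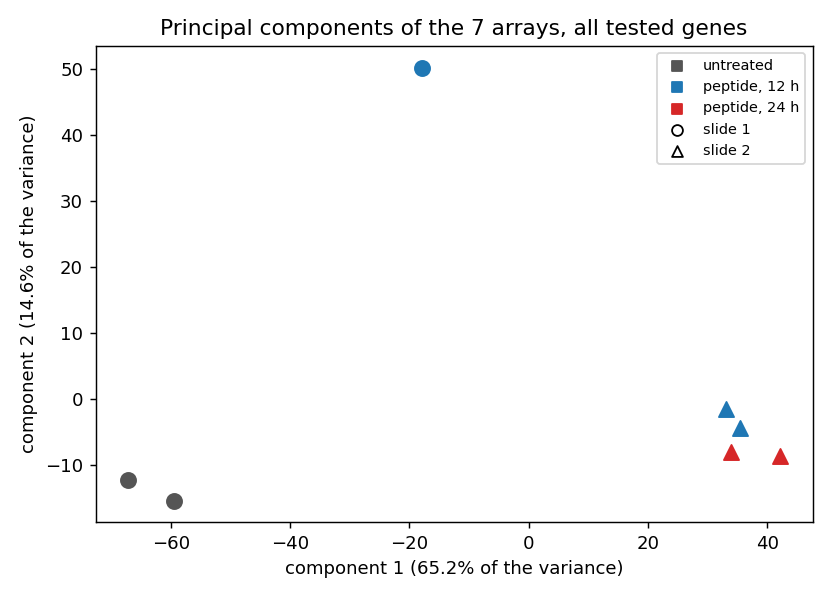
Position of the 7 arrays on the first (horizontal, 65.2% of the variance) and second (vertical, 14.6%) principal component of all 19658 tested genes, with colour for the group and shape for the slide. The untreated arrays lie at −59.4 and −67.1 on the first component, 12 h replicate 1 of slide 1 at −17.9, and the 4 treated arrays of slide 2 between 33.1 and 42.1.

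The first comparison asked how 12 h of the peptide changed the transcriptome. TCN1, which encodes a cobalamin-binding protein, rose from −2.49 ± 0.01 to 2.27 ± 0.02 (change 4.76, SE 0.08, 27.1-fold, adjusted p = 5.75e-05). PIP, which encodes a secreted protein of exocrine glands, rose by 3.97 (SE 0.09, 15.7-fold), and TXNIP, which encodes an inhibitor of thioredoxin, rose by 3.71 (13.04-fold). ALOX5, the gene of the enzyme that starts leukotriene synthesis, rose by 3.56 (11.8-fold). The adhesion molecule genes CEACAM6 and CEACAM7 rose by 3.59 (12.0-fold) and 3.54 (11.6-fold), with the limit that probes of this family may bind each other's transcripts. SPOCK1, which encodes a matrix proteoglycan, had the largest fall among genes well above background on all untreated and 12 h arrays, from −0.48 ± 0.03 to −4.20 ± 0.14 (change −3.72, SE 0.20, adjusted p = 0.00049). With the slide term these 7 changes lay between −3.74 and 4.75 and all passed.

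Further falls at 12 h were those of NIPAL4, a membrane protein gene (−2.79, SE 0.15), BCAT1, which encodes the cytosolic branched-chain aminotransferase (−2.49, SE 0.11), DCLK1, which encodes a microtubule-associated kinase (−2.41), and RTN4RL1, which encodes a Nogo receptor homologue (−2.40, SE 0.26). The probes of BCAT1 and of RTN4RL1 did not read alike, and those of RTN4RL1 ranged from −2.40 to 0.55. The BCAT1 call was lost on the deposited series values (−0.56, adjusted p = 0.514), and that of RTN4RL1 there (0.0623) and with the mean of its probes (−0.93, 0.148). KCNMA1, a calcium-activated potassium channel gene, fell by 3.01 (SE 0.54, adjusted p = 0.016), but the call was lost with the slide term (−2.96, adjusted p = 0.0725). It was also lost without untreated replicate 1 (0.0796) or 2 (0.0938) or without 12 h replicate 2 (0.0537) or 3 (0.0534), and over all its alternatives the adjusted p ran from 0.00114 to 0.0938. Among genes not well above background in untreated cells, BPIFB1, which encodes an airway secretory protein, was at least 23.9-fold higher at 12 h, and GUCA2B, the uroguanylin gene, at least 25.5-fold (adjusted p = 0.000189 and 0.000252). The snoRNA gene SNORA30 was at least 4.14-fold lower, and FOXS1, a forkhead factor gene, at least 3.75-fold lower. The FOXS1 call (adjusted p = 0.0124) was lost without untreated replicate 1 or 2 and with the slide term (adjusted p = 0.0531, with a range of 0.00201 to 0.0936 over its alternatives).

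**Figure D2:**
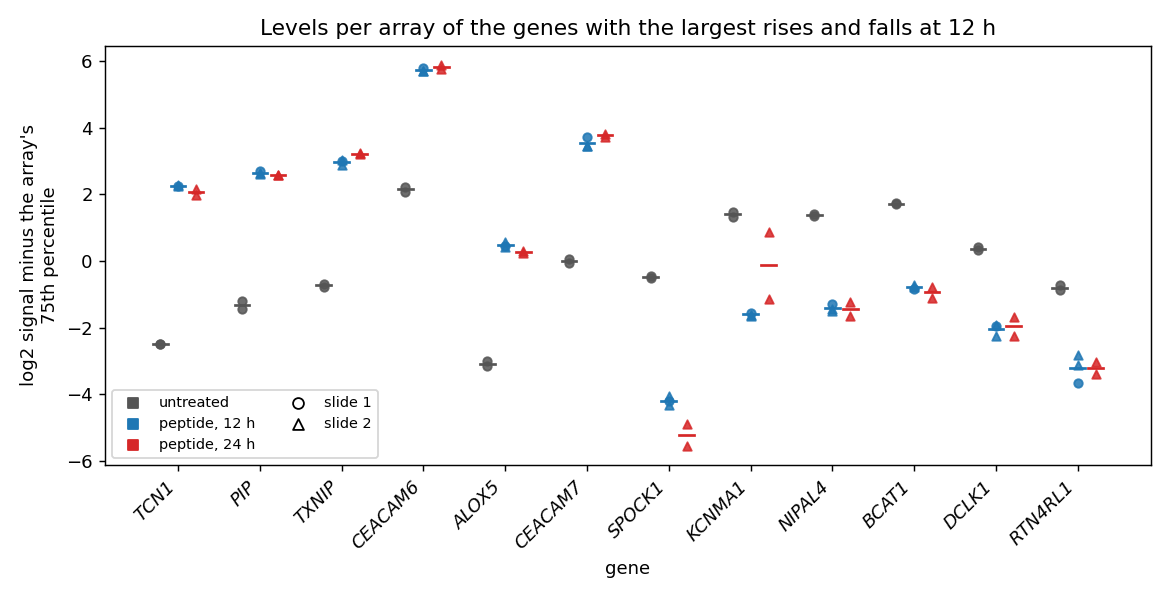
Level per array (log2 signal relative to the 75th percentile of the array) of the 6 genes with the largest rises and the 6 with the largest falls at 12 h, where points are arrays, horizontal bars are group means, colour marks the group and shape the slide. TCN1 lies at 2.27 on average at 12 h against −2.49 in untreated cells, and KCNMA1 is the gene whose 24 h arrays lie farthest apart (SD 1.42, n = 2).

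The positions of these probes on hg19 are as follows. The probe of TCN1 spans chromosome 11, 59620762 to 59622151. PIP lies at chromosome 7, 142836745 to 142836804, TXNIP at chromosome 1, 145442447 to 145442506, and CEACAM6 at chromosome 19, 42275434 to 42275493. SPOCK1 lies at chromosome 5, 136311187 to 136311246, and SUB1 on the same chromosome at 32591694 to 32591753. MDM2 lies at chromosome 12, 69233570 to 69233629, and CDKN1A at chromosome 6, 36652178 to 36652237.

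The genes nearest to the question of the series moved less. SUB1 stood at 4.05 ± 0.10 in untreated cells and 3.68 ± 0.13 at 12 h, a difference of −0.36 (SE 0.12) that did not pass (adjusted p = 0.0809, and −0.24 with the slide term). Over 19 alternatives the adjusted p of SUB1 ran from 0.0207 to 0.354 and passed in 3, among them the fit without 12 h replicate 1 (−0.43, adjusted p = 0.0377). CDKN1A, the gene of the cell-cycle inhibitor p21, differed by −0.07 (SE 0.18, adjusted p = 0.781), with the opposite sign under the slide term (0.27). MDM2, which encodes the ubiquitin ligase of p53, differed by 0.48 (SE 0.17, adjusted p = 0.0855), and the apoptosis gene BAX by −0.25 (adjusted p = 0.145). BBC3, which encodes the pro-apoptotic protein PUMA, rose by 0.37 (SE 0.09, adjusted p = 0.0399), and GDF15, which encodes a stress-induced cytokine, rose by 0.45 (SE 0.11, adjusted p = 0.0398). Both calls were lost with the slide term (BBC3 0.43, adjusted p = 0.0858, and GDF15 0.57, adjusted p = 0.0538) and without any one array other than 12 h replicate 1. Their adjusted p ran from 0.00917 to 0.696 for BBC3 and from 0.00623 to 0.496 for GDF15, and each passed in 7 of 19 alternatives.

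Of 43 measured p53 target genes, 5 rose, 6 fell and 32 did not pass at 12 h, and the counts were also 5 and 6 when adjusted over the list alone. Where a list below has no second count, the count over the list alone was the same number. TRIM22, an interferon- and p53-induced gene, was at least 1.71-fold higher and TP53INP1, a gene of the p53 stress response, rose by 0.48. DDB2, which encodes a damage-recognition protein of nucleotide excision repair, fell by 0.64 (SE 0.09, adjusted p = 0.00871), CCNG1, which encodes cyclin G1, fell by 0.68, and FBXO22, which encodes an F-box protein, fell by 0.63. The list did not shift as a whole (median −0.10, −0.05 with the slide term, camera adjusted p = 0.265). Of 20 p53 regulators and partners, 1 rose (PPP1R13B, which encodes a p53-binding activator of apoptosis, 0.66) and 5 fell, among them MDM4 (−0.55) and the checkpoint kinase gene CHEK1 (−0.75), with a median of −0.13 (adjusted p = 0.105). With the slide term 1 of the p53 targets rose and 1 fell, and without 12 h replicate 1, 6 rose and 12 fell. Of 25 pro-apoptotic genes 1 rose and 4 fell, led by HRK (−1.42, SE 0.21, adjusted p = 0.00886) and BOK (−0.54), at a median of −0.14 (adjusted p = 0.167). The probes of BCL2L11 disagreed (−0.39 to 1.47). Of 10 anti-apoptotic genes 1 rose (BIRC3, 0.56) and 1 fell (CFLAR, −0.40; 1 and 2 over the list alone), with a median of −0.04 that turned to 0.05 under the slide term (adjusted p = 0.576).

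The lists of G1/S and DNA replication and of G2 and mitosis passed at 12 h. Of 34 measured G1/S and DNA replication genes, 21 fell and none rose over all genes tested (26 fell when adjusted over the list alone, 5 over all genes with the slide term), with a median of −0.41 (−0.32 with the slide term, adjusted p = 1.42e-08, but adjusted p = 0.659 with an estimated correlation). POLE2, a DNA polymerase epsilon subunit gene, fell by 1.03 (SE 0.14), MCM7, a gene of the replicative helicase, by 0.65 and the DNA replication gene MCM10 by 0.54. Of 34 G2 and mitosis genes, 13 fell (17 over the list alone, 2 with the slide term) at a median of −0.36 (−0.20 with the slide term, adjusted p = 6.94e-07, and adjusted p = 0.659 with an estimated correlation). CCNB1, the cyclin B1 gene, and CDC20, an activator of the anaphase-promoting complex, each fell by 0.57. The 23 replication-dependent histone genes held none that passed (median 0.03 while the test pointed down, adjusted p = 0.980).

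Among repair genes at 12 h, 10 of 27 of double-strand break repair fell (13 over the list alone, 4 with the slide term), including XRCC2 (−0.81), FANCA (−0.61) and RAD54L (−0.61), genes of homologous recombination and crosslink repair. Their median was −0.34 (−0.20 with the slide term, adjusted p = 2.8e-05, and adjusted p = 0.659 with an estimated correlation). Of 18 base excision repair genes 6 fell (7 over the list alone, 1 with the slide term), among them the ligase gene LIG3 (−0.62) and the glycosylase genes MUTYH (−0.54) and NEIL2 (−0.68). The list had a median of −0.22 (−0.16 with the slide term, adjusted p = 0.0011, and adjusted p = 0.659 with an estimated correlation). Of 17 nucleotide excision repair genes only ERCC8 passed (−0.59), and the median was −0.11 (adjusted p = 0.230).

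Of 30 genes of ribosome biogenesis and MYC targets, 19 fell at 12 h (26 over the list alone, 6 with the slide term), at a median of −0.46 (−0.41 with the slide term, adjusted p = 5.56e-09, but adjusted p = 0.659 with an estimated correlation). Examples were NOP2, a nucleolar methyltransferase gene (−0.66), RRS1, a ribosome assembly gene (−0.69), and POLR1B, an RNA polymerase I subunit gene (−0.72). Of 27 spliceosome genes 5 fell, among them U2AF2 (−0.45) and SF3A3 (−0.41), and of 28 proteasome genes 2 fell, PSMD12 (−0.47) and PSMC6 (−0.44), which passed over all genes but not over the list alone. Their medians were −0.26 and −0.21 (−0.22 and −0.16 with the slide term, adjusted p = 4.11e-05 and 0.00014, and adjusted p = 0.659 with an estimated correlation for both), with no single member passing under the slide term, while without 12 h replicate 1, 12 and 11 fell. The 42 cytosolic ribosomal protein genes lay at a median of −0.10 (−0.04 with the slide term, adjusted p = 0.00748) with 1 fall, RPLP2 (−0.29), and none over the list alone. That list gave adjusted p = 0.855 with an estimated correlation, and its call was lost with the slide term (0.238), within slide 1 (0.322), with directional fry (0.120) and without untreated replicate 1 (−0.08, 0.0934). The 31 oxidative phosphorylation genes (median −0.04, adjusted p = 0.409) held 1 fall, CYC1 (−0.52), and the 15 reference housekeeping genes (median −0.04, adjusted p = 0.696) held 1 rise, GUSB (0.36), and 1 fall.

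Of 29 genes of TGF-beta, matrix and mesenchymal cells, 16 fell and 1 rose at 12 h (17 and 1 over the list alone, 9 and 1 with the slide term). SPARC, which encodes a matrix glycoprotein, fell by 1.76 (SE 0.12, adjusted p = 0.000889), and COL5A1, a collagen gene, by 0.92, whereas FN1, the fibronectin gene, rose by 1.39. The list's median was −0.50 (−0.30 with the slide term, adjusted p = 3.59e-05, and adjusted p = 0.659 with an estimated correlation). Of 25 heat shock genes 11 fell (16 over the list alone, 4 with the slide term), led by the chaperone genes HSPA8 (−1.15, SE 0.12) and HSPA1A (−0.64), while the small heat shock protein gene CRYAB rose by 1.69. Their median was −0.34 (−0.33 with the slide term, adjusted p = 6.94e-05, and adjusted p = 0.659 with an estimated correlation).

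The 3 lists that rose at 12 h each had a median below 0 under median scaling, where their calls were lost. That scaling moves every gene of a comparison by the same constant. The median of all genes went from 0.02 to −0.25 at 12 h and from −0.02 to −0.30 at 24 h. The distance of each list median from that of all genes therefore stayed the same, and the medians of falling lists moved down alike. Of 22 epithelial and alveolar genes, 9 rose and 1 fell (11 and 2 over the list alone, 6 and 0 with the slide term), with rises of the water channel gene AQP3 (1.48, SE 0.12), the keratin gene KRT19 (1.44, SE 0.10) and the mucin gene MUC1 (1.46, but −0.75 with adjusted p = 0.00963 on the deposited series values), and a fall of the tight junction gene CLDN1 (−0.48). Their median was 0.26 (0.35 with the slide term, adjusted p = 0.0144), it turned to −0.02 under median scaling (0.0524), and the call was lost without 12 h replicate 1 (0.28, 0.0856) and on the deposited series values (0.20, 0.121). That list had adjusted p = 0.659 with an estimated correlation. Of 30 genes of cholesterol and fatty acid synthesis, 11 rose and 1 fell (12 and 2 over the list alone, 9 and 0 with the slide term), including INSIG1, a gene of sterol control (1.12). Their median was 0.20 (0.26 with the slide term, adjusted p = 0.000442, and adjusted p = 0.659 with an estimated correlation) and turned to −0.08 under median scaling (0.0635). Of 24 NRF2 and antioxidant genes, 5 rose and 1 fell (2 and 0 with the slide term), with GPX2, a glutathione peroxidase gene, at 1.40 and HMOX1, the haem oxygenase gene, at −0.52. Their median of 0.11 (0.20 with the slide term, adjusted p = 0.047, and adjusted p = 0.659 with an estimated correlation) turned to −0.16 under median scaling (0.543). The call was also lost without untreated replicate 1 (0.17, 0.0522) or 2 (0.106), without 12 h replicate 1 (0.291), without 24 h replicate 2 (0.0578), with the replicate block (0.0529) and with only the 2 groups in the fit (0.0544).

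Other lists did not pass at 12 h. Of 30 genes of the unfolded protein and ATF4 response 3 rose and 9 fell (7 and 10 over the list alone), with the transcription factor gene ATF3 at 2.25 and the amino acid synthesis genes ASNS and PHGDH both at −1.23 (median −0.20, adjusted p = 0.146). Of 19 NF-kappaB and inflammatory genes 5 rose and 2 fell (5 and 4 over the list alone), with the chemokine gene CXCL8 at 1.63 and the cytokine gene IL6 at −1.79. That list's median of −0.01 turned to 0.17 under the slide term, and the test pointed up (adjusted p = 0.766). Of 29 interferon-stimulated genes 9 rose and 2 fell (11 and 3 over the list alone), with BST2 at 1.47, OAS1 at 1.00 and HERC5 at −0.98 (median 0.10, adjusted p = 0.167). Of 26 immediate early genes 3 rose and 5 fell (3 and 6 over the list alone), with MYC at −1.24, JUNB at −1.21 and DUSP2 at least 1.30-fold higher (median −0.17, 0.07 with the slide term, adjusted p = 0.490). Of 29 hypoxia and glycolysis genes 4 rose and 4 fell, with the carbonic anhydrase gene CA9 at 2.26 and PFKFB3, a glycolysis enzyme gene, at −0.73 (median 0.02 while the test pointed down, adjusted p = 0.766). Of 29 autophagy and lysosome genes 6 rose and 1 fell (7 and 1 over the list alone), with GABARAPL1 at 1.31 and NPC1 at −0.59 (median 0.07, adjusted p = 0.0845, and 0.0193 with the slide term). Of 7 metallothionein genes MT1F rose by 1.12 (median 0.08, adjusted p = 0.334).

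Markers of cell types other than epithelium were tested too. Of 12 measured leukocyte markers CD14 (0.85) and CD68 (1.07) rose and ITGAM fell (−0.45), and the median of 0.96 dropped to 0.11 with the slide term (adjusted p = 0.0543 and 0.696). That list passed in 8 of 22 alternatives, among them the fit without 12 h replicate 1 (median 1.25, adjusted p = 0.00437, 7 rises). Of 6 fibroblast and endothelial markers, LUM was at least 3.12-fold higher and THY1 (−1.37), COL1A1 (−0.50) and ACTA2 (−0.48) fell (2 rose and 3 fell over the list alone). The median of that list was −0.36 and its mean 0.26 (adjusted p = 0.546).

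Over all genes, 4648 of 19658 changed at 12 h by limma (2301 higher and 2347 lower), and 1054 of them by at least 1 (789 and 265). The slide term left 2409 (1538 and 871), of which 2055 were called by both fits. Within slide 1, where 12 h replicate 1 faced both untreated arrays, limma called 0 genes (4694 had an unadjusted p under 0.05). In 366 called genes a group was not well above background. Both groups did not overlap in 11278 genes (57.4%, where chance gives 20%). Under median scaling the median of all genes moved from 0.02 to −0.25 and the share of higher calls from 49.5% to 24.9%, against 63.8% with the slide term. The count was 9239 without 12 h replicate 1, 1403 and 1178 without untreated replicates 1 and 2, 2088 and 2103 without 12 h replicates 2 and 3, and 3050 without either 24 h array. Of the 60 named calls at 12 h, 27 and 28 were lost without untreated replicates 1 and 2, 12 without 12 h replicate 2 and 12 without replicate 3, 6 without either 24 h array and 0 without 12 h replicate 1. That last fit raised the falls in most lists, for example to 19 in double-strand break repair, 24 in G2 and mitosis, 8 in p53 regulators, 8 in pro-apoptotic genes and 8 in cytosolic ribosomal proteins. In it slide and treatment coincided, so the added calls may come from either. All 13 list calls were lost with an estimated correlation, and over their alternatives the adjusted p ran from 5.59e-11 to 0.855.

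**Figure D3:**
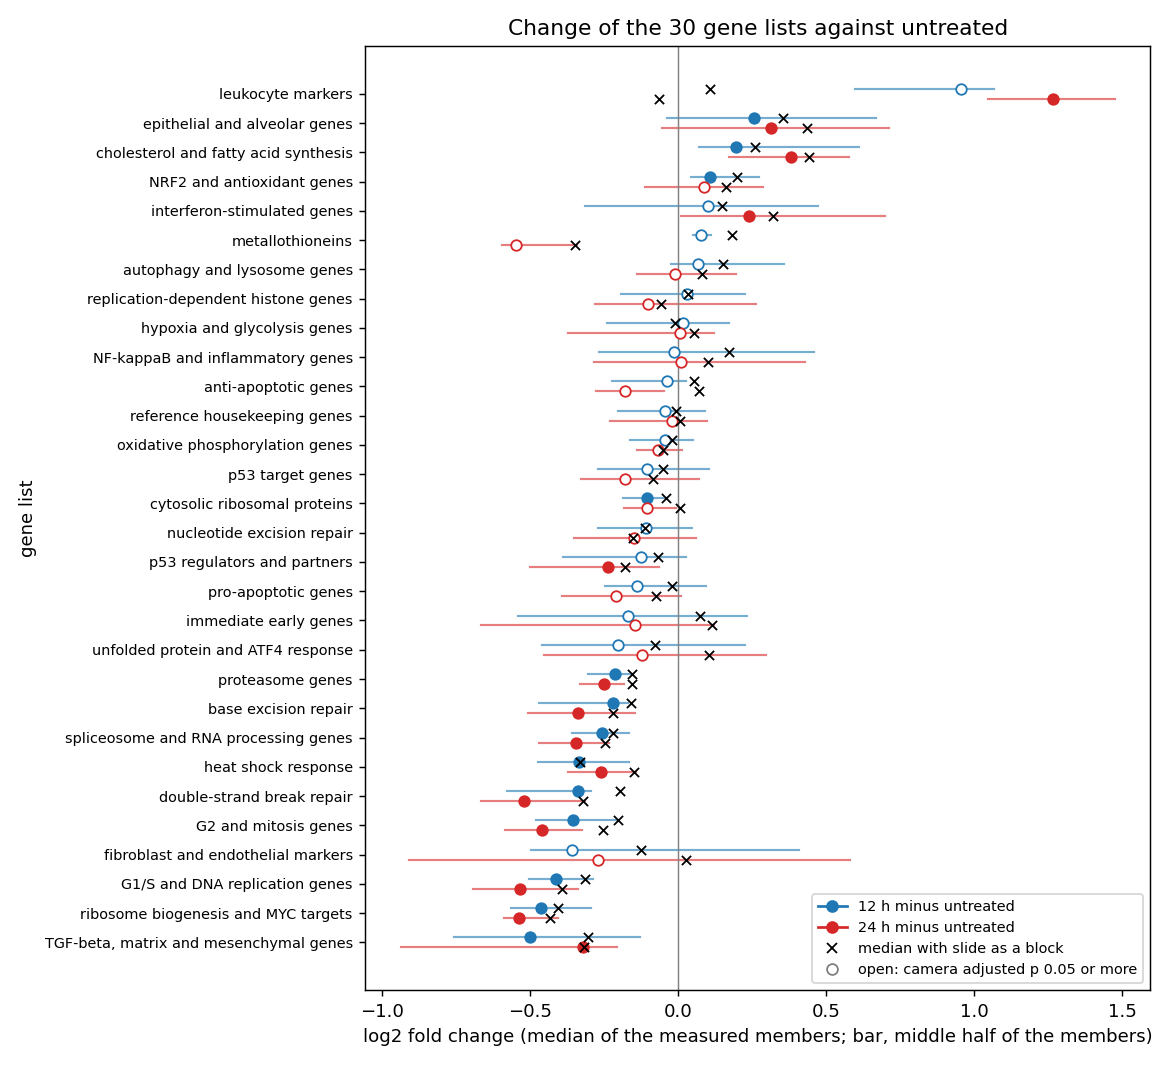
Median log2 change against untreated (horizontal) of the measured members of each of the 30 lists (vertical) at 12 h and 24 h, with bars for the interquartile range of members, filled points where the adjusted p of camera passed and crosses for the median with the slide term. At 12 h ribosome biogenesis (−0.46) and G1/S (−0.41) lie low while epithelial genes lie at 0.26 (−0.02 under median scaling), cholesterol synthesis at 0.20 (−0.08) and NRF2 genes at 0.11 (−0.16), and at 24 h interferon-stimulated genes lie at 0.24 (−0.05) and leukocyte markers at 1.27 (−0.06 with the slide term). Median scaling moves all genes of a comparison, falling lists included, by the same constant.

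The second comparison set 24 h of the peptide against untreated cells. TCN1 was again the largest measured rise, to 2.07 ± 0.14 (change 4.56, 23.6-fold, adjusted p = 0.000113), followed by TXNIP (3.96, 15.6-fold) and PIP (3.91, 15.1-fold). CEACAM7 rose by 3.78 (13.7-fold), VTCN1, which encodes an immune checkpoint ligand, by 3.69 (12.9-fold) and CEACAM6 by 3.67 (12.8-fold). GUCA2B was at least 40.2-fold and BPIFB1 at least 30.7-fold higher. GREM1, the gene of a BMP antagonist, fell by 2.98 (SE 0.17, adjusted p = 0.000663), and SPOCK1 was at least 22.6-fold lower (adjusted p = 0.000437). NIPAL4 fell by 2.83, NPTX1, which encodes a neuronal pentraxin, by 2.78, BCAT1 by 2.66, and the homeobox genes BARX1 and HOXD10 by 2.73 and 2.49. FOXS1 was at least 4.64-fold lower. With the slide term all of these passed except FOXS1 (adjusted p = 0.0526, and 0.00459 without the term, with a range of 0.000476 to 0.0526), and no single left-out array ended any of these calls. The BCAT1 call was lost with the mean of its probes (−1.29, adjusted p = 0.0812) and on the deposited series values (−0.30, 0.754). No slide held both groups, so the slide term borrows the slide difference from the 12 h arrays.

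SUB1 stood at 3.61 ± 0.17 at 24 h, a difference of −0.43 from untreated (SE 0.13) that did not pass (adjusted p = 0.0594, and −0.24 with adjusted p = 0.493 under the slide term). Over 18 alternatives the adjusted p of SUB1 ran from 0.0192 to 0.493 and passed in 5. BAX differed by −0.33 (adjusted p = 0.0844), BBC3 by −0.07 (adjusted p = 0.606) and GDF15 by 0.26 (adjusted p = 0.154). CDKN1A differed by −0.15 (SE 0.20, adjusted p = 0.572) and by 0.36 with the slide term. MDM2 rose from −0.30 ± 0.02 to 0.64 ± 0.20 (change 0.94, SE 0.18, adjusted p = 0.0197), but its probes ranged from −0.34 to 0.94 and the call was lost with the slide term (0.53, adjusted p = 0.193). The MDM2 call passed in 9 of 18 alternatives (adjusted p from 0.00331 to 0.627) and was lost without untreated replicate 1 (0.0871) or 2 (0.0936) or without 24 h replicate 1 (0.0524) or 2 (0.115).

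Of the 43 p53 targets, MDM2, TP53INP1 (0.52) and TRIM22 (at least 1.70-fold) rose at 24 h, 7 fell and 33 did not pass (3 rose and 5 fell over the list alone), at a median of −0.18 (−0.08 with the slide term, adjusted p = 0.129). Those that fell included DDB2 (−0.63), the adrenodoxin reductase gene FDXR (−0.63), CCNG1 (−0.68) and the sestrin gene SESN1 (−0.59), and with the slide term none of the 43 passed, while without 12 h replicate 1, 5 rose and 13 fell. Among p53 regulators and partners 1 rose and 6 fell (1 and 9 over the list alone, 1 and 0 with the slide term), with CHEK1 at −0.93, HMGB1 at −0.64 and the kinase gene ATM at −0.50. Their median was −0.24 (adjusted p = 0.0464, but adjusted p = 0.670 with an estimated correlation and −0.18 with adjusted p = 0.322 under the slide term). That call was also lost without untreated replicate 2 (0.0613), without 24 h replicate 2 (0.0700), with quantile normalisation (0.0942), with the stricter filter on dim probes (0.0986) and with the replicate block (0.0546). Of the pro-apoptotic genes 0 rose and 5 fell, with HRK at −1.43 and BOK at −0.69 (median −0.21, adjusted p = 0.0706). Of the anti-apoptotic genes BIRC3 rose (0.39) and CFLAR (−0.46) and BIRC5 (−0.40) fell (median −0.18, 0.07 with the slide term, adjusted p = 0.271).

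Of the 34 G1/S genes 24 fell at 24 h (26 over the list alone, 2 with the slide term), with MCM10 at −0.86 and the origin recognition gene ORC1 at −0.95, at a median of −0.53 (−0.39 with the slide term, adjusted p = 6.84e-09, but adjusted p = 0.659 with an estimated correlation). Of the 34 G2 and mitosis genes 19 fell (29 over the list alone, 0 with the slide term), with CCNB1 at −0.70 and the checkpoint kinase gene BUB1B at −0.77, at a median of −0.46 (−0.26 with the slide term, adjusted p = 6.46e-08, and adjusted p = 0.659 with an estimated correlation). Of the 27 double-strand break repair genes 18 fell (21 fell and 1 rose over the list alone, 1 fell with the slide term), with XRCC2 at −1.08 and RAD54L at −0.81, at a median of −0.52 (−0.32 with the slide term, adjusted p = 3.32e-06, and adjusted p = 0.659 with an estimated correlation). Of the 18 base excision repair genes 9 fell (11 over the list alone, 0 with the slide term), with MUTYH at −0.64, NEIL3 at −0.76 and the polymerase gene PARP1 at −0.51, at a median of −0.34 (−0.22 with the slide term, adjusted p = 0.000669, and adjusted p = 0.659 with an estimated correlation). Of the nucleotide excision repair genes ERCC8 (−0.52) and ERCC1 (−0.48) fell, and none over the list alone (median −0.15, adjusted p = 0.258). No histone gene passed (median −0.10, adjusted p = 0.604).

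Of the 30 ribosome biogenesis genes and MYC targets, 22 fell at 24 h (27 over the list alone, 0 with the slide term), with MYC itself at −1.36 (SE 0.20, adjusted p = 0.0101) and WDR12, a ribosome assembly gene, at −0.92. The median was −0.54 (−0.43 with the slide term, adjusted p = 1.31e-08, but adjusted p = 0.659 with an estimated correlation). Of the spliceosome genes 13 fell (20 over the list alone, 0 with the slide term), with SRSF7 at −0.67 and SNRNP70 at −0.58, and of the proteasome genes 6 fell (0 over the list alone, 0 with the slide term), with PSMD12 at −0.58. Their medians were −0.34 and −0.25 (−0.25 and −0.15 with the slide term, adjusted p = 6.87e-05 and 0.000141, and adjusted p = 0.659 with an estimated correlation for both). Of the heat shock genes 2 rose and 6 fell (2 and 10 over the list alone, 0 and 0 with the slide term), with HSPA8 at −0.74 (0.16 on the deposited series values) and CRYAB at 1.08, at a median of −0.26 (−0.15 with the slide term, adjusted p = 0.0115, and adjusted p = 0.659 with an estimated correlation). Of the TGF-beta, matrix and mesenchymal genes 13 fell and 1 rose (17 and 1 over the list alone, 5 and 0 with the slide term), with SPARC at −2.46 (SE 0.13), COL5A1 at −1.46 and FN1 at 1.35. Their median was −0.32 (−0.32 with the slide term, adjusted p = 4.3e-05, and adjusted p = 0.659 with an estimated correlation).

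Of the 30 cholesterol and fatty acid genes 17 rose and 1 fell at 24 h (8 and 0 with the slide term), with INSIG1 at 0.85 and ACLY at −0.56. Their median was 0.38 (0.44 with the slide term, adjusted p = 3.76e-06, but adjusted p = 0.659 with an estimated correlation), and 0.09 under median scaling. Of the epithelial genes 7 rose and 2 fell (11 and 2 over the list alone, 6 and 0 with the slide term), with AQP3 at 1.82, KRT19 at 1.47, the claudin gene CLDN4 at 1.43 (−0.25 on the deposited series values) and EPCAM at −0.37, at a median of 0.31 (0.44 with the slide term, adjusted p = 0.0125, and adjusted p = 0.659 with an estimated correlation). Under median scaling that median was 0.03 and the call was lost (0.0642), as it was on the deposited series values (0.0958) and with only the 2 groups in the fit (0.0579). Of the interferon-stimulated genes 11 rose and 3 fell (13 and 3 over the list alone, 4 and 0 with the slide term), with BST2 at 1.28, IFIT2 at 0.99 (−1.37 on the deposited series values) and ISG20 at 0.70 against HERC5 at −1.40 and ISG15 at −0.74. Their median of 0.24 (0.32 with the slide term, adjusted p = 0.0229, and adjusted p = 0.659 with an estimated correlation) turned to −0.05 under median scaling (0.193), and the call was lost without 12 h replicate 1 (0.0712), on the deposited series values (0.16, 0.2002) and with only the 2 groups in the fit (0.0782). Of the leukocyte markers CD14 (0.86), CD68 (1.18) and CD79A (1.80) rose, at a median of 1.27 that fell to −0.06 with the slide term (adjusted p = 0.00748 and 0.533, and adjusted p = 0.659 with an estimated correlation). The CD79A call passed in 8 of 18 alternatives and was lost with the slide term (0.53, adjusted p = 0.293, with a range of 0.00179 to 0.293) and without either untreated array, either 24 h array or 12 h replicate 3.

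The remaining lists did not pass at 24 h. Of the 7 metallothionein genes MT1F rose (0.77) and 5 fell, among them MT1X (−0.55) and MT1H (−0.75), with 1 and 6 over the list alone, at a median of −0.55 (−0.35 with the slide term, adjusted p = 0.0714). Of the unfolded protein and ATF4 genes 7 rose and 9 fell (8 and 9 over the list alone), with ATF3 at 2.05, XBP1 at 0.66 and ASNS at −1.28 (median −0.12, 0.10 with the slide term, adjusted p = 0.409). Of the NF-kappaB genes 7 rose and 3 fell, with CXCL8 at 2.13 and IL6 at −1.55 (median 0.01, adjusted p = 0.589). Of the NRF2 genes 5 rose and 1 fell (median 0.09, adjusted p = 0.167, and 0.0187 with the slide term). Immediate early genes had 3 rises and 4 falls (3 and 5 over the list alone, median −0.15, 0.11 with the slide term, adjusted p = 0.412), hypoxia and glycolysis genes 4 and 5 (4 and 6 over the list alone, median 0.01 while the test pointed down, adjusted p = 0.766), and autophagy and lysosome genes 5 and 1 (median −0.01 while the test pointed up, adjusted p = 0.625). Cytosolic ribosomal proteins had 0 and 1 (median −0.11, adjusted p = 0.0628, passing in 8 of 21 alternatives). With the slide term their median was 0.00562 and the camera test did not pass (adjusted p = 0.832). Oxidative phosphorylation genes had 0 and 2 (−0.07, adjusted p = 0.265), and both of these lists had 0 and 0 over the list alone. Housekeeping genes had 1 and 2 (−0.02, adjusted p = 0.766). Of the fibroblast and endothelial markers LUM (at least 2.69-fold) and CDH5 (0.85) rose and THY1 (−1.55) and COL1A1 (−1.11) fell (2 and 3 over the list alone, median −0.27, mean 0.16, adjusted p = 0.604).

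Over all genes, 5379 changed at 24 h by limma (2478 higher and 2901 lower), and 1532 by at least 1 (1164 and 368). The slide term left 1075 (737 and 338), of which 932 were called by both fits. In 459 called genes a group was not well above background, and 15420 genes (78.4%) did not overlap between the groups, where chance gives 33.3%. Under median scaling the median of all genes moved from −0.02 to −0.30 and the share of higher calls from 46.1% to 30.03%, against 68.6% with the slide term. The count was 9324 without 12 h replicate 1, 1457 and 1160 without untreated replicates 1 and 2, and 1833 and 1035 without 24 h replicates 1 and 2. Of the 65 named calls, 25 and 26 were lost without untreated replicates 1 and 2, and 16 and 30 without 24 h replicates 1 and 2. Without 12 h replicate 1 the falls numbered 29 in G2 and mitosis, 19 in spliceosome, 11 in proteasome, 12 in heat shock, 10 in p53 regulators, 8 in pro-apoptotic and 7 in cytosolic ribosomal protein genes, and 7 leukocyte markers rose. No treated array lay on slide 1 in that fit, so slide and treatment coincided. All 14 list calls were lost with an estimated correlation, and their adjusted p over the alternatives ran from 9.69e-11 to 0.670.

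Both comparisons share the untreated arrays. They had 1732 of the 2301 genes higher at 12 h in common, where independent lists of these sizes would give 290, and 1923 of the 2347 lower genes, where such lists would give 346, and ID4, named after its values were seen, was the 1 gene called in opposite directions (0.52 at 12 h and −0.54 at 24 h). Across genes, which are not independent replicates, the changes correlated at 0.914 (slope 1.095) with a covariance of 0.395. In 100 simulations of unchanged groups against the same controls the covariance averaged 0.0333 (at most 0.0375), the correlation 0.547 and the number of shared calls 0.01. The covariance exceeded the simulated one by 0.362, and over the 6 pairs of 12 h and 24 h arrays it ran from 0.239 to 0.488. The 2 untreated arrays cannot be split into parts of 2, so part of the excess in shared calls may come from the shared controls. The simulations drew noise independently per gene and held no slide difference. Both comparisons set mainly slide 2 arrays against untreated arrays of slide 1, so a slide difference may also add to the covariance and the shared calls. With the slide term the covariance was 0.309, but both estimates then rest on 12 h replicate 1 and the untreated arrays.

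The third comparison asked what changed between 12 h and 24 h of the peptide. No single gene passed, so the following values are of genes with the smallest p. HP and SAA1, genes of acute-phase proteins, stood 1.03 and 1.14 higher at 24 h, and TEF, a clock-controlled transcription factor gene, 1.099 higher (adjusted p = 0.266 for each). ID4, which encodes an inhibitor of helix-loop-helix factors, stood at −1.07, XYLT1, a xylosyltransferase gene, at −1.01 and KCNMB4, a potassium channel subunit gene, at −0.83 against 12 h (adjusted p = 0.266 for each). ID4 passed with normexp (−0.91, adjusted p = 0.0369) and with the trended robust fit (−1.07, 0.0162), and its adjusted p ran from 0.0162 to 0.602 over 19 alternatives. SUB1 differed by −0.07 (adjusted p = 0.842), CDKN1A by −0.08 (0.883), BAX by −0.08 (0.801), GDF15 by −0.19 (0.663), BBC3 by −0.44 (0.395) and MDM2 by 0.46 (0.522).

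The clearest group difference was in metallothioneins, small metal-binding proteins. All 7 measured genes were lower at 24 h than at 12 h when adjusted over the list alone and none over all genes, with MT1X at −0.70, MT1E at −0.68, MT1H at −0.66 and MT1B at −0.61. Their median was −0.61 and −0.53 within slide 2 (adjusted p = 1.78e-08, but adjusted p = 0.659 with an estimated correlation). Probes of this family may bind each other's transcripts, and those of MT1E ranged from −0.68 to 0.05.

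The other lists that passed between the times shifted less, and no member passed over all genes or over the list alone. Double-strand break repair lay at −0.18 (adjusted p = 0.00192, and adjusted p = 0.659 with an estimated correlation), with BRCA2 at −0.40, and at −0.11 within slide 2 (adjusted p = 0.0628 there). Its median was −0.11 without 12 h replicate 1 and −0.09 without 24 h replicate 2. G1/S genes lay at −0.11 (adjusted p = 0.00116, and adjusted p = 0.698 with an estimated correlation), with MCM10 at −0.32, at −0.08 with the slide term, and at −0.06 without 24 h replicate 2 (0.114). G2 and mitosis genes lay at −0.12 (adjusted p = 0.00689, and adjusted p = 0.784 with an estimated correlation), at −0.05 with the slide term (0.329) and at −0.05 without 12 h replicate 1 (0.298). Autophagy and lysosome genes lay at −0.10, with GABARAPL1 at −0.37, and at −0.08 with the slide term (adjusted p = 0.00155, and adjusted p = 0.659 with an estimated correlation). Heat shock genes lay at 0.09 with and without the slide term, with HSPA8 at 0.41 (adjusted p = 0.00231, and adjusted p = 0.659 with an estimated correlation), and at 0.06 without 24 h replicate 1 (0.0741). Cholesterol and fatty acid genes lay at 0.06, with the lanosterol synthase gene LSS at 0.37, and at 0.13 with the slide term (adjusted p = 0.00116, and adjusted p = 0.659 with an estimated correlation), and between 0.03 and 0.13 without 24 h replicate 1 and 12 h replicate 1. Median scaling ended the calls of heat shock (0.077) and cholesterol genes (0.0708). Leukocyte markers lay at 0.40 (adjusted p = 0.0243, and adjusted p = 0.659 with an estimated correlation), but at 0.02 with the slide term (0.480) and without 12 h replicate 1 (0.409), at 0.33 without 24 h replicate 2 (0.114) and at 0.19 without the filter on dim probes (0.196). Directional fry ended the calls of double-strand break repair (0.181), G2 and mitosis (0.303), G1/S (0.175), heat shock (0.144), cholesterol (0.104) and leukocyte genes (0.358).

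The remaining 22 lists did not pass between the times. Their medians lay between −0.11 (anti-apoptotic genes, adjusted p = 0.129) and 0.08 (interferon-stimulated genes, adjusted p = 0.1497), with p53 targets at −0.06 (0.258), p53 regulators at −0.08 (0.253) and pro-apoptotic genes at −0.07 (0.172). TGF-beta and matrix genes lay at −0.10 (0.135) with a median of −0.00267 under the slide term. Adjusted over the list alone, the matrix genes SPARC (−0.70), COL1A1 (−0.60, also a fibroblast marker) and COL5A1 (−0.54) and the stress gene NDRG1 (−0.60) were lower at 24 h. The factor gene SNAI2 (0.63), the cytokine gene IL1B (0.48) and the aldolase gene ALDOC (0.67) were higher in the same way, and these 7 genes were chosen after their values were seen.

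Over all genes, limma called 0 between 24 h and 12 h, while 1786 had an unadjusted p under 0.05 and 983 would by chance. The slide term (1973 unadjusted) and the arrays of slide 2 alone (1989) also gave 0, and 5639 genes (28.7%) did not overlap, where chance gives 20%. Without 24 h replicate 1 the count was 5, with KCNMA1, OASL, CLDN15, MPZL2 and XLOC_006187 named after their values were seen (adjusted p = 0.0251 each). All 8 list calls were lost with an estimated correlation, and their adjusted p over the alternatives ran from 9.69e-11 to 0.784.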

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

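The tests of the list differences between 12 h and 24 h were fixed before the data were examined, and the test of denser culture was written before its result was seen, while the tests of slide, array response, GC content, single arrays and cross-binding probes, and the fit of probes without a gene name, were chosen after the results they concern were seen.

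Metallothionein genes differed between the 2 treatment times by a median of −0.61 (24 h minus 12 h), lower in 7 of 7 measured genes when adjusted over the list alone. Over all genes 0 of them passed, and camera with an estimated correlation did not call the list (adjusted p = 0.659). The slide as the cause is argued against, since within slide 2, where both times were present, the median was −0.53, with an SD of 0.132 over members. A single 24 h array is argued against too, since within slide 2 the median stayed at −0.38 without 24 h replicate 2 and −0.66 without 24 h replicate 1. A single signal read by all 7 probes would have to move alike at 12 h against untreated, but the members then spread over 1.21 on the log2 scale. That spread rests on MT1F, which rose while the others did not pass, so cross-binding among the other 6 stays open, as does a real effect of treatment time, which no separate measurement tested.

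The 12 h arrays differed between the slides: replicate 1, on slide 1, differed by over 1 from the mean of replicates 2 and 3 in 1678 genes, lower in 1575 and higher in 103, and 78.8% of these genes lay nearer to the untreated arrays (73.6% and 74.7% with either untreated array alone). A uniform response of replicate 1 between 25 and 75% of that on slide 2 would, without scatter, place the genes in that range. Of 2678 genes changed by over 1 on slide 2, 25.0% reached between 25 and 75% of that change, 42.3% less and 32.7% more. The scatter of single arrays, which spreads such ratios, was not modelled, so a uniformly smaller response stays open. Within probes of 40 to 45% GC the share lower by over 1 was 21.0% for genes without a current symbol and 4.52% for the rest. GC content acting alike on all genes would give like shares. These 2 classes were not matched for signal level, and the share was 30.2% in the lowest class of level and 2.92% in the highest. The comparison therefore cannot separate GC content from level as the cause. GC content as a partial cause stays open, since that share rose from 3.20% in the lowest GC band to 26.6% in the highest, although the rank correlation of the slide difference with GC over all genes, the form tested first, was −0.08. Between replicates of one group on one slide that correlation was larger in size: 0.257 for untreated, −0.179 for 12 h replicates 2 and 3, and −0.216 for 24 h. Slide, scan and culture batch cannot be told apart here, because the 12 h group was the only one on both slides, and a slide term called 1832 genes, 1649 of them higher on slide 2.

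The change against untreated was large at both times (4648 and 5379 genes). The slide alone is argued against as the cause, since the change of 12 h replicate 1 against 1 untreated array of its own slide had a slope of 0.378 or 0.465 on the change of the slide 2 arrays against the other untreated array, where a slide effect alone predicts a slope near 0. Denser culture in the treated arrays stays open: 22 target genes of YAP and TAZ, which fall in dense cultures, had medians of −0.22 at 12 h and −0.19 at 24 h (0.00469 and 0.0183 with the slide term), with 4 rises at each time and 7 and 8 falls. Camera did not pass (unadjusted p = 0.341 and 0.267, and 0.810 and 0.633 with the slide term). An effect of the peptide stays open beside handling and time in culture, since no array of a control peptide was analysed here.

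The other lists that differed between the times by camera were double-strand break repair (−0.18), G2 and mitosis (−0.12), G1/S and DNA replication (−0.11), autophagy and lysosome (−0.10), heat shock (0.0923), cholesterol and fatty acid synthesis (0.0561) and leukocyte markers (0.40), none of which passed with an estimated correlation. Of 917 probes that carry no gene name and enter no comparison of genes, 122 changed at 12 h (80 higher and 42 lower) and 163 at 24 h (124 and 39), against untreated arrays as controls, and limma called 0 between the times.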

How the results depend on the processing

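The fits without 12 h replicate 1 were singled out after the data were examined, and all other settings here were fixed before. In those fits slide and treatment coincided, so calls kept there do not test a slide effect. A total of 23 settings were run. Of 125 called results of named genes, 24 kept their call in all alternatives run for them, none of them at 12 h. The fit within slide 1 was run for 12 h but not for 24 h and called 0 genes, so this count does not compare the times. Over these gene results, 1856 alternative values kept the call, 436 lost it and 8 turned direction, and over the 35 called list results 672 kept it and 84 lost it. List results not called gained a call in 86 alternative values, 43 of them with mixed fry. Among the lost list calls the median changed sign in 5: NRF2, cholesterol and epithelial genes at 12 h and interferon-stimulated genes at 24 h under median scaling, and leukocyte markers at 24 h with the slide term. Under median scaling every gene of a comparison moves by the same constant. Sign changes there therefore come from the scaling of all genes and not from a list's distance to them. Of the 125 gene results, 0 were lost under quantile normalisation, 0 without 12 h replicate 1 and 9 under median scaling. Another 37 were lost without the filter on dim probes, 53 with the slide term and 56 with the replicate block. Over all genes, quantile normalisation called 4169 of the 4648 again at 12 h and 4649 of the 5379 at 24 h. Within slide 1 all 60 of the named calls at 12 h were lost. The cause was not tested unless a construction is named. Signal over background limits what can be said of dim genes, of which 30.2% in the lowest class of level were lower by over 1 in 12 h replicate 1, against 2.31 to 2.92% in the 2 highest classes. The lone array left in a group by leaving out its partner was assumed to vary like the other groups.

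The count at 12 h against untreated (4648) was 1054 with an absolute change of at least 1, 1681 without the filter, 2409 with the slide term, 3050 with only the 2 groups in the fit, and from 1178 to 9239 without single arrays. Within slide 1 it was 0 (limma, 4694 at an unadjusted p under 0.05), where 3 arrays leave 1 residual degree of freedom. The count at 24 h (5379) was 1532, 1562, 1075 and 7992 under the same 4 settings in turn, and from 1035 to 9324 without single arrays. Without 12 h replicate 1, 4616 of the 4648 and 5379 of the 5379 genes were called again, in a fit that cannot separate treatment from slide. Between 24 h and 12 h limma gave 0 (1786 at an unadjusted p under 0.05), normexp 1 and the trended robust fit 1 (ID4 in both), the deposited values 4 (GIGYF2, ANTXR2, PTGS1 and PSG1, named after their values were seen), and the fits without single arrays from 0 to 5. The covariance of the 12 h and 24 h changes (0.395) was 0.147 with normexp, whose offset shrinks changes of dim genes by construction. It was 0.309 with the slide term and from 0.357 to 0.469 without single arrays.

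The 35 list calls became 0 with an estimated correlation and 77 with the mixed form of fry, which by construction counts changes in either direction. With directional fry 34 passed, of which 28 were among the 35, and the calls ran from 31 to 41 without single arrays. Within single slides 19 list tests passed where 21 had passed before. With the mean of its probes BCL2L11 turned from −0.39 to 0.45 at 12 h and from −0.45 to 0.88 at 24 h, since its probes disagree. The deposited table averages the probes well above background on each array, so that the probes entering a gene differ between arrays, and there BCL2L11 was at 0.48 and 0.91, MUC1 at −0.75 (12 h), CLDN4 at −0.25, HSPA8 at 0.16 and IFIT2 at −1.37 (24 h).

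No pairing by replicate number was seen: deviations from the group means of same-numbered arrays correlated between −0.104 and 0.0884, where every pair would have to exceed 0.1. In groups of 2 arrays the deviations mirror each other by construction. At 12 h those of replicate 1 ran against those of replicates 2 and 3 (−0.793 and −0.764). A pairing could therefore be masked and is not excluded. With the replicate block, which costs degrees of freedom, the count at 12 h was 802, at 24 h 1525 and between the times 0, the list calls numbered 33 and the covariance was 0.360. Only 12 h replicate 3 carried the number 3, so the block also takes that array out of the 12 h estimate. The covariance without 12 h replicate 3 was likewise 0.360.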

Other observations

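All tests in this part were chosen after the changes of single genes had been seen: every stem of gene symbols with at least 8 measured members was taken as a family and tested with camera, adjusted over 235 families and 3 comparisons. In all, 85 of 705 family tests passed, 40 also with the slide term, and none with an estimated correlation (adjusted p = 0.938 or more for each), which holds for every call below. Of 8 CEACAM genes 5 rose at 12 h and 5 at 24 h (medians 2.37 and 2.76, adjusted p = 5.22e-05 and 2.47e-05, medians 2.44 and 2.86 with the slide term), with CEACAM1 at 1.72 and 2.21. Of 10 mucin genes (MUC) 7 rose at each time (median 1.40 at both, adjusted p = 0.000234 and 0.000134, medians 1.18 and 1.03 with the slide term). Of 36 keratin genes (KRT) 15 rose at each time and 1 fell at 24 h (medians 0.74 and 1.03, 0.34 and 0.36 with the slide term). Of 10 galectin genes (LGALS), which encode sugar-binding proteins, 7 and 6 rose (medians 0.78 and 0.99, 0.72 and 0.79 with the slide term). Of 9 HOXB homeobox genes 7 rose and 1 fell at 24 h (median 0.58, adjusted p = 0.0237, median 0.70 with the slide term), and under median scaling 1 rose (median 0.29).

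Other families fell at both times. Of 50 mitochondrial ribosomal protein genes of the large subunit (MRPL) 14 and 16 fell (medians −0.27 and −0.31, −0.19 and −0.16 with the slide term), and of 29 of the small subunit (MRPS) 13 fell at each time and 1 rose at 12 h (−0.31 and −0.32, −0.23 and −0.21 with the slide term). Of 22 nucleoporin genes (NUP) 10 and 11 fell (−0.31 and −0.44, −0.27 and −0.34 with the slide term), and of 36 DDX helicase genes 12 and 11 fell (−0.29 and −0.33, −0.22 and −0.21 with the slide term). Of 88 SNORA genes, which encode small nucleolar RNAs, 34 fell at 12 h and 29 fell and 1 rose at 24 h (medians −0.45 and −0.33, adjusted p = 1.89e-06 and 0.00206, medians −0.45 and −0.37 with the slide term). Of 87 SNORD genes 24 fell and 2 rose at 12 h (median −0.40, −0.28 with the slide term), and at 24 h 20 fell and 3 rose (−0.37), but the shift did not hold with the slide term (−0.12, adjusted p = 0.482). Between the times both stood higher at 24 h (SNORA 0.18 and SNORD 0.07, adjusted p = 6.82e-05 and 0.0109, and 0.18 for each with the slide term), although no single member passed. Labelling started from an oligo-dT primer, which favours polyadenylated RNA. Cross-binding of probes among members of a family was not tested here. The directions named here were the same under quantile and median scaling. The rise of keratin-associated protein genes (KRTAP) did not hold with the slide term. Of 46, 9 rose at 12 h and 13 at 24 h (medians 0.76 and 1.08), whereas with the slide term the medians were 0.08 and 0.10 (camera adjusted p = 0.677 and 0.758). That term rests on 12 h replicate 1, so slide, array and culture batch cannot be told apart for this family. Of the 1649 genes called higher on slide 2, 58.9% had no current symbol or a symbol not listed as protein coding, against 25.8% of the rest. Genes without a current symbol are of unknown type. Among all tested genes they numbered 4159, against 1467 with a symbol not listed as protein coding.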
